A study of Mus musculus with 17 samples.

How the data were processed

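RNA of sorted intestinal stem cells from LGR5-GFP knock-in mice, in which a green fluorescent protein reports Lgr5, was measured on 17 single-colour Agilent mouse arrays. The cells had been sorted as LGR5hi or LGR5lo, from mice given 12 Gy of gamma-irradiation or none, and per the labels the measurement was at 3 hours. There were 4 arrays of non-irradiated LGR5hi cells, 5 of non-irradiated LGR5lo cells, 4 of irradiated LGR5hi cells and 4 of irradiated LGR5lo cells. Each group held 2 female arrays, and the others were male. Replicates 1 and 2 of every group lay on one slide, replicates 3 and 4 on another, and non-irradiated LGR5lo replicate 5 alone on the last.

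The deposited scanner files hold linear Cy3 intensity per spot, which the authors' software, Agilent Feature Extraction 10.7.3.1, had subtracted for background and detrended. No normalization between arrays had been applied to these per the file headers. The deposited series table holds log2 values. Their construction was worked out from the values, since no tool for it is given in the sources used here: log2 signal minus the array's 75th percentile, then minus each probe's median over the 17 arrays. The scanner file of non-irradiated LGR5hi replicate 1 is damaged as held here, with 15329 of 62976 spots readable. Its values were therefore rebuilt from the series table and each probe's baseline on the other arrays. After removal of a constant, the rebuilt values lay within 0.02 log2 of the readable part for 100% of 13423 probes, so the level of that array was not checked. The file header gives the array's 75th percentile as 412, but the level was not tested against it. On the 16 arrays with whole files the same rebuilding met that tolerance for 99.4% to 99.8% of probes with no constant removed. No spot flags were available for the rebuilt array, so presence above background in non-irradiated LGR5hi cells is out of 3 arrays.

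Values were log2 processed signals minus the array's 75th percentile over non-control probes, after spots with an outlier flag were left out and replicate spots averaged. Of 55681 non-control probes, 41480 were well above background on at least 4 arrays and were kept. Gene symbols were updated through RefSeq accessions for 2837 of the 27229 probes that matched the gene table. For each gene name the kept probe with the highest mean over all arrays was tested, which gave 27799 names, 17961 of them in the gene table. The arrays' number limits the precision: the median standard error of a log2 difference was 0.26 for irradiation in LGR5hi and 0.36 for the difference of the irradiation effects.

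Group means were fitted over all 17 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The comparisons were irradiated minus non-irradiated within each sort, the difference between these effects, LGR5hi minus LGR5lo within each arm, female minus male, and the irradiation effect in females minus that in males. Errors beside log2 differences are standard errors of the fit. A fold against a group with no array above background is given only as a lower bound. Non-irradiated LGR5lo replicate 2, with 95.6% of spots above background, can alone keep its group from this rule. The 24 gene lists were written from general knowledge and tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists within a comparison. Camera was repeated with an estimated correlation, and fry was run as a test of each list on its own. Exact permutation tests of list means are two-sided. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

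The comparisons, gene lists, main settings, alternative analyses and the rule for named genes were chosen before the data were examined. The rule takes the 8 largest rises and 8 largest falls among called genes whose compared groups do not overlap, up to 4 members of each list with the smallest p, and Lgr5, Olfm4, Ascl2, Cdkn1a, Mdm2, Ccng1, Bbc3, Bax and Trp53. Names that are only clone, contig or accession identifiers were passed over. Of the genes that this rule takes, 1 is left out of the text. For the difference of effects, the largest called differences were taken. Those alternatives were quantile normalization, median centring, normexp background correction with an offset of 50 (on 16 arrays), no filter and a stricter filter on dim probes, the mean of a gene's probes, the series table's values, sex as a covariate, replicate number or slide as a block, arm and number as a random block, array weights, a trended and robust variance, fits of only the compared groups, and each array left out in turn. A block for scan date was not run, as the dates followed the slides. Fits without particular arrays, within single slides, and with number as a block within each arm were added after the data had been seen.

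Same-numbered LGR5hi and LGR5lo arrays of one arm deviated from their group means together, with correlations across genes of 0.116 to 0.338 without irradiation and 0.162 to 0.450 after it, each higher than with any other number. Numbers were therefore read as pairing the sorts within an arm, although the labels do not name a shared mouse or pool. Same-numbered arrays of an arm also share slide, row and sex, which may add to these correlations. For irradiated replicate 4 the margin was small, with 0.162 against 0.161 for another number. Across arms own-number correlations were the highest in 1 of 8 cases, so numbers there were not read as pairs. Each group occupied its own column on both slides with 8 arrays, so there column and irradiation or sort cannot be told apart. Non-irradiated LGR5lo replicate 5 lay in column 4 of its slide, the column of irradiated LGR5lo cells on the others. The list mean of p53 targets over the non-irradiated LGR5lo arrays, this one included, was -0.08 (SD 0.11), against 2.02 after irradiation. As a single array alone on its slide, it separates column from irradiation only in part. Females lay in row 1 of the slide in the non-irradiated arm and in row 2 in the irradiated arm, and males the reverse, so the row on the slide and the sex by irradiation term are the same contrast.

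The pipeline was tested on simulated data with 50 changed genes per size. A change of 2 log2 was recovered for 70% of genes for irradiation in LGR5hi, 68% in LGR5lo and 54% for the difference of effects, and a change of 1 log2 for 40%, 42% and 16%. Of the unchanged genes 10, 6 and 5 were called falsely in these comparisons. A shifted list of 27 genes was called by camera in each of the 5 comparisons run with lists. Of the lists without a shift, 1 was called falsely for irradiation in LGR5lo and 0 in the other comparisons. The simulated noise was independent between genes and arrays, while the measured G2 and mitosis list had an estimated correlation of 0.518. The simulation therefore does not test false calls for lists whose genes vary together, or for paired arrays. Far fewer genes were changed in it than limma called for irradiation. The adjusted threshold depends on that number, so the recovery for irradiation in the measured data may differ.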

Results

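The series holds genome-wide RNA measurements of LGR5hi and LGR5lo cells, sorted by flow cytometry from LGR5-GFP reporter mice, with and without 12 Gy of gamma-irradiation. Lgr5 is a receptor for R-spondins and the marker of cycling stem cells at the base of intestinal crypts. Groups were non-irradiated LGR5hi (n = 4), non-irradiated LGR5lo (n = 5), irradiated LGR5hi (n = 4) and irradiated LGR5lo (n = 4). The 75th percentile of the signal ranged from 323 to 702 intensity units over the arrays, and from 58.9% to 73.9% of spots were well above background on 16 of them. Non-irradiated LGR5lo replicate 2 stood apart, with 95.6% of spots above background and a spike-in slope of 0.79. On that array the median deviation from the rest of its group was 2.38 log2 for the dimmest of 5 equal classes of genes and -0.58 log2 for the brightest. The counts of called genes are therefore also given without it. No spike-in slope above 0 was recorded for non-irradiated LGR5lo replicate 4.

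**Figure D1:**
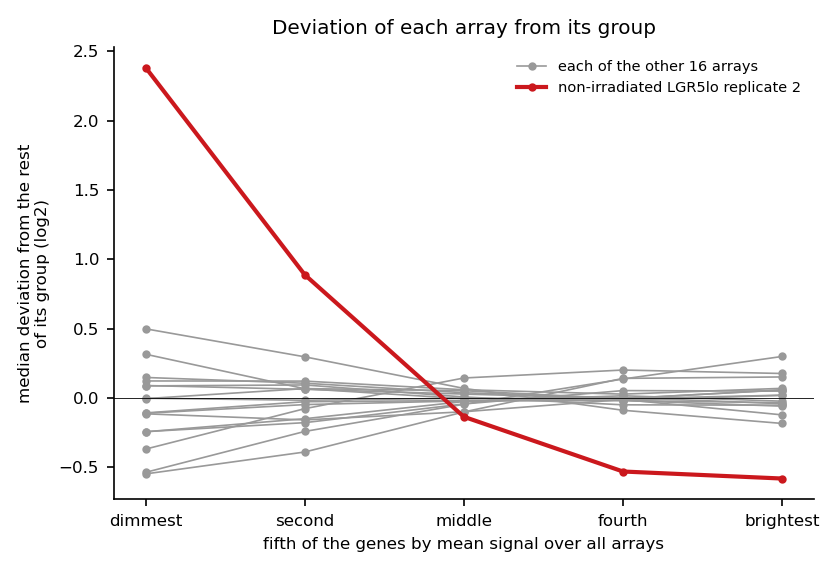
Median log2 deviation of each array from the rest of its group, for 5 equal classes of genes ordered by mean signal; one line per array. Non-irradiated LGR5lo replicate 2 runs from 2.38 in the dimmest class to -0.58 in the brightest.

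The series was made to derive the signatures of the response to irradiation in each population, which for LGR5hi cells compares 4 irradiated with 4 non-irradiated arrays. In LGR5hi cells most of the tested p53 targets, immediate early and NF-kB genes rose, and most of those of G2 and mitosis fell. The largest rise was that of Zfp365, a p53-responsive gene that protects fragile sites, at 9.04 ± 0.52 log2 (NM_178679; mm9 chromosome 10, 67348908 to 67348967), although its probe was above background on only 1 of 3 non-irradiated LGR5hi arrays. It was followed by the membrane transporter gene Slc4a11 (8.91 ± 0.47), the tubulin gene Tubb6 (8.35 ± 0.50) and Crip2 (7.34 ± 0.23). Next came the receptor ligand gene Areg (7.31 ± 0.45), the receptor gene Notch3 (7.26 ± 0.32) and Anxa8 (7.0 ± 0.4, with the lower of its probes at 2.89). Dhh, a hedgehog ligand gene, was above background only after irradiation and was at least 58.2-fold higher. The largest fall was in Sfrp5, a secreted WNT inhibitor gene, at -5.45 ± 0.35 (NM_018780; chromosome 19, 42272509 to 42272568). Next were the reductase gene Akr1c14 (-5.25 ± 0.91), Prelp (-4.17 ± 0.38), the histone gene H2bc23 (-3.93 ± 0.54), Pimreg (-3.79 ± 0.36) and the gene of the peptide neurotensin, Nts (-3.64 ± 0.60). Fank1 was at least 8.59-fold lower and Cenpf, a kinetochore gene, at least 6.44-fold lower, with no irradiated array above background. In all, limma called 3743 of 27799 genes, 1715 higher and 2028 lower, of which 1113 and 992 changed at least 2-fold. Without the array that stands apart the call covered 5193 genes (2363 higher, 2830 lower). With slide as a block it covered 4234, on slide 1 alone (2 arrays per group) 266 and on slide 2 alone 1571.

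Of 50 p53 targets, 39 rose in LGR5hi cells and 0 fell, or 41 and 1 adjusted over the list alone. The median change was 2.30 log2 (camera adjusted p = 1.86e-46, and 0.00076 with an estimated correlation). Among them were Phlda3, an inhibitor of AKT signalling (5.66 ± 0.23), the kinase gene Plk2 (4.97 ± 0.22) and Ccng1 (4.03 ± 0.18). Cdkn1a, which encodes the cell cycle inhibitor p21, went from -0.17 ± 0.82 to 4.74 ± 0.25 (normalized log2 signal, SD, n = 4 each), a rise of 4.91 ± 0.31 by its brightest probe and 3.25 by its lowest. Mdm2, the gene of the p53 ubiquitin ligase, rose by 3.15 ± 0.29, and the transcript of p53 itself, Trp53, was 0.27 ± 0.19 (adjusted p = 0.48). In the BCL2 family, which regulates mitochondrial apoptosis, 7 of 19 genes rose and 3 fell (8 and 3 adjusted over the list alone). The death-promoting members Bbc3 (3.29 ± 0.29), Bax (2.64 ± 0.18) and Pmaip1 (2.30 ± 0.26) rose and the likewise death-promoting Bmf fell (-2.26 ± 0.24). Bbc3, Bax and Pmaip1 are also members of the p53 list, so the results of these lists are not independent. The family's camera adjusted p was 0.0413, but 0.341 with an estimated correlation and 0.0605 without the array that stands apart. The list mean of the p53 targets changed by 2.51 on slide 1, 2.28 on slide 2 and 2.40 with slide as a block.

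Of 48 genes of G2 and mitosis, 45 fell and 1 rose, the same adjusted over the list alone. The median was -1.68 log2 (adjusted p = 4.94e-37, and 0.0393 with an estimated correlation). Falls included Cdkn3 (-3.41 ± 0.26), the spindle gene Nusap1 (-2.93 ± 0.24) and the phosphatase gene Cdc25b (-2.73 ± 0.24). The member that rose was Gtse1, at 2.81 ± 0.26, known as a p53-inducible gene. The list mean changed by -1.63 on slide 1, -1.77 on slide 2 and -1.70 with slide as a block. Of 45 genes of G1 to S and DNA replication 7 fell and 0 rose (13 and 0 adjusted over the list alone), among them Tk1 (-1.49 ± 0.25) and E2f8 (-1.38 ± 0.24). The median was -0.43 and the adjusted p 6.14e-05, but 0.494 with an estimated correlation. Of 52 DNA repair genes 15 fell and 0 rose (20 and 0 adjusted over the list alone), with Bard1 at -1.11 ± 0.20 and H2ax at -1.22 ± 0.24. The median was -0.34 and the adjusted p 1.95e-06, but 0.341 with an estimated correlation. Their list means moved by -0.37 and -0.41 with slide as a block.

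Of 44 LGR5 stem cell markers, 21 fell and 1 rose (24 and 2 adjusted over the list alone). The median was -0.67 log2 and the adjusted p 1.55e-09, but 0.193 with an estimated correlation. Lgr5 fell by 1.53 ± 0.29 (adjusted p = 0.0019), Cdo1 by -2.97 ± 0.17, the vitamin D receptor gene Vdr by -2.12 ± 0.19 and Ascl2, a transcription factor gene of these stem cells, by -0.94 ± 0.23, while Olfm4 was -0.27 ± 0.24 (adjusted p = 0.60). The list mean moved by -0.72 on slide 1 and -0.76 on slide 2. Of 16 markers of reserve or injury-associated stem cells, 8 rose and 1 fell (10 and 1 adjusted over the list alone). The median was 1.23 (adjusted p = 1.95e-06, and 0.0016 with an estimated correlation). Besides Areg these were led by Ly6a (6.62 ± 0.41), the gene of the Sca-1 surface antigen, and the EGF family gene Ereg (3.99 ± 0.46), and Hopx fell (-1.08 ± 0.18). The list mean moved by 1.91 on slide 1 and 1.77 on slide 2. Of 28 WNT targets 2 rose and 6 fell (2 and 7 adjusted over the list alone; adjusted p = 0.13), with Cd44 at 1.88 ± 0.18 and Tcf7 at -0.71 ± 0.16. Of 24 secretory progenitor and Notch genes 3 rose and 2 fell (3 and 4 adjusted over the list alone; adjusted p = 0.85), with the Notch ligand genes Jag2 at 4.19 ± 0.29 and Jag1 at 1.39 ± 0.19 and the Notch modifier gene Lfng at -2.95 ± 0.24.

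Of 32 immediate early and dissociation stress genes, 18 rose and 0 fell (22 and 2 adjusted over the list alone). The median was 1.35 log2 (adjusted p = 5.81e-11, and 0.0067 with an estimated correlation). They were led by the AP-1 gene Fosl1 (4.95 ± 0.31), Egr1 (2.92 ± 0.38) and Ier3 (2.62 ± 0.28). This list also answers to tissue dissociation and sorting, which all groups underwent. Of 27 NF-kB and inflammatory genes 17 rose and 2 fell, the same adjusted over the list alone, with a median of 1.52 (adjusted p = 3.03e-11, and 0.0026 with an estimated correlation). Among them were the chemokine gene Cxcl16 (3.91 ± 0.18), Nfkb2 (2.77 ± 0.24) and the inhibitor gene Nfkbia (2.17 ± 0.19). Of 42 ribosome biogenesis genes 13 rose and 0 fell (19 and 0 adjusted over the list alone), with Utp20 at 1.85 ± 0.12. The median was 0.46 and the adjusted p 5.81e-11, but 0.307 with an estimated correlation. The 3 list means moved by 1.25, 1.49 and 0.43 on slide 1 and by 1.22, 1.78 and 0.56 on slide 2.

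None of the lists of markers of mature and non-epithelial cells passed camera for irradiation in LGR5hi cells. Counts that follow are members higher and lower, the same adjusted over the list alone unless given. They were 1 and 1 of 23 Paneth, 1 and 2 of 21 goblet, 2 and 6 of 35 enteroendocrine (2 and 8 over the list alone), 1 and 1 of 27 tuft, 0 and 4 of 41 enterocyte, 1 and 0 of 32 leukocyte, 1 and 0 of 20 stromal and endothelial, and 0 and 1 of 8 erythrocyte markers. The medians were 0.42, -0.20, -0.22, -0.22, -0.32, 0.13, 0.09 and -0.81 log2. Single members that rose were the goblet list's S100a6 (2.81 ± 0.40), the tuft list's Alox5 (2.06 ± 0.29), the collagen gene Col4a1 (3.04 ± 0.47), Cd79b (1.41 ± 0.26) and the tachykinin gene Tac1 (1.62 ± 0.27), and the alpha-globin gene Hba-a1 fell (-1.17 ± 0.35). The Hba-a1 call was lost without any of non-irradiated LGR5hi replicates 1, 2 and 3 or irradiated LGR5hi replicates 1, 2 and 4.

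**Figure D2:**
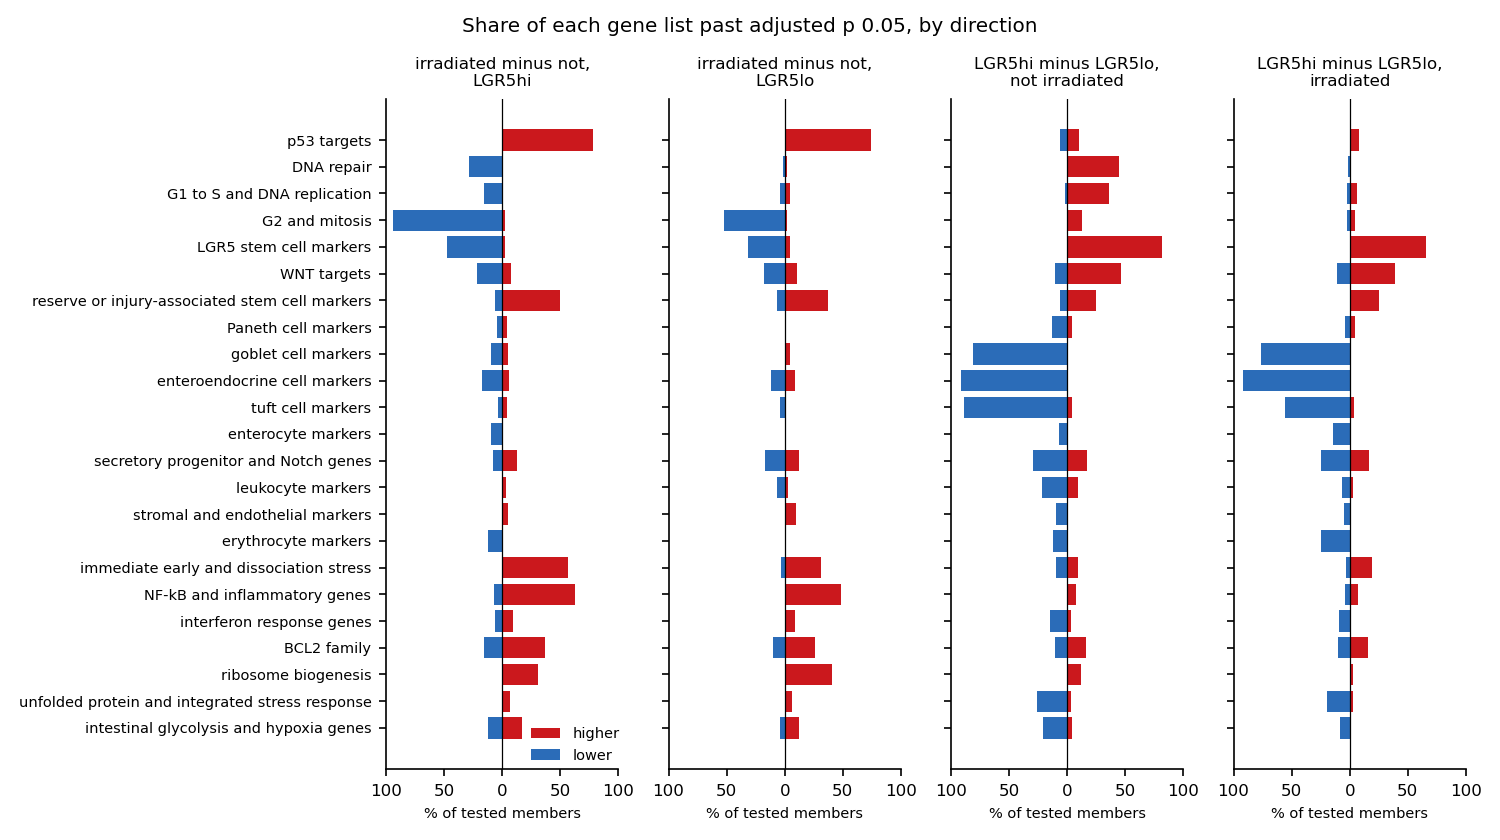
Share of the tested members of each gene list (percent) with an adjusted p under 0.05, higher to the right and lower to the left, in 4 comparisons. In LGR5hi cells 39 of 50 p53 targets rose and 45 of 48 genes of G2 and mitosis fell; before irradiation 32 of 35 enteroendocrine markers were lower in LGR5hi cells.

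The same question was asked of LGR5lo cells with 4 irradiated and 5 non-irradiated arrays. Most of the tested p53 targets rose here too. The largest rises were those of Slc4a11 (8.05 ± 0.45), Tubb6 (6.66 ± 0.48), Notch3 (6.46 ± 0.31), Inka2 (6.35 ± 0.59, with probes from 4.26), Anxa8 (6.30 ± 0.38, with probes from 2.58), Crip2 (6.21 ± 0.21), Zfp365 (6.09 ± 0.50) and the lactoferrin gene Ltf (6.01 ± 0.29). The largest falls were those of Prelp (-3.65 ± 0.36), Pimreg (-3.55 ± 0.34), Sfrp5 (-3.45 ± 0.33), H2bc23 (-3.22 ± 0.51), Wfdc16 (-3.19 ± 0.55) and the urea transporter gene Slc14a1 (-3.00 ± 0.26). The defensin gene Defb40 was at least 2.58-fold lower and Rab3il1 at least 3.1-fold lower. In all, limma called 2070 genes, 1242 higher and 828 lower, with 645 and 390 of them changed at least 2-fold. The count was 2542 (1373 and 1169) without the array that stands apart, and 1272, 1178 and 1267 without irradiated LGR5lo replicates 1, 3 and 4. With slide as a block it was 2319, on slide 1 alone 44 and on slide 2 alone 459. The median over all genes was -0.13 log2 and 0.12 after median centring, where 1051 genes were called higher and 222 lower, so the share of rises depends on the scaling.

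Of 50 p53 targets, 37 rose in LGR5lo cells and 0 fell (43 and 2 adjusted over the list alone). The median was 1.99 log2 (adjusted p = 8.81e-51, and 0.00048 with an estimated correlation). Phlda3 rose by 6.0 ± 0.2, Gdf15, a secreted stress cytokine gene, by 5.63 ± 0.25, Ccng1 by 3.87 ± 0.17, Mdm2 by 2.95 ± 0.28 and Cdkn1a by 2.90 ± 0.30 (probes from 2.31 to 3.63), and Trp53 was 0.25 ± 0.18 (adjusted p = 0.39). In the BCL2 family 5 of 19 genes rose and 2 fell (7 and 2 adjusted over the list alone), with Bbc3 at 3.55 ± 0.28, Bax at 2.25 ± 0.17 and Pmaip1 at 1.89 ± 0.24. The adjusted p was 0.0019, but 0.138 with an estimated correlation. Of 48 genes of G2 and mitosis 25 fell and 1, Gtse1 (2.69 ± 0.24), rose (38 and 1 adjusted over the list alone). The median was -0.87 and the adjusted p 9.50e-16, but 0.230 with an estimated correlation. Cenpf (-2.85 ± 0.33) and Cdkn3 (-2.26 ± 0.25) were among those that fell. On slides 1 and 2 the mean of the p53 list moved by 2.12 and 2.05 and that of the mitosis list by -0.92 and -1.09.

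Of 44 LGR5 stem cell markers 14 fell in LGR5lo cells and 2 rose (19 and 3 adjusted over the list alone). The median was -0.47 log2 and the adjusted p 0.00045, but 0.617 with an estimated correlation. The list mean went from -0.48 to -0.23 after median centring. Lgr5 fell by 1.27 ± 0.28, Ascl2 by -1.07 ± 0.22 and Cdo1 by -2.25 ± 0.16, the growth factor gene Pdgfa rose by 1.33 ± 0.19, and Olfm4 was -0.38 ± 0.22 (adjusted p = 0.29). Of 16 reserve or injury-associated markers 6 rose and 1 fell, the same adjusted over the list alone, with a median of 0.65 (adjusted p = 8.92e-05, and 0.0044 with an estimated correlation). They were led by Areg (5.97 ± 0.42), Ly6a (4.31 ± 0.39) and Ereg (3.07 ± 0.44). Of 32 immediate early genes 10 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 0.71 (adjusted p = 6.63e-08, and 0.0247 with an estimated correlation). Among those with the smallest p were Fosl1 (3.48 ± 0.29) and Egr1 (1.81 ± 0.36). Of 27 NF-kB and inflammatory genes 13 rose and 0 fell (15 and 3 adjusted over the list alone), with a median of 1.05 (adjusted p = 1.61e-11, and 0.0037 with an estimated correlation). By smallest p these included Cxcl16 (3.51 ± 0.17) and Nfkbia (1.92 ± 0.18). Of 42 ribosome biogenesis genes 17 rose and 0 fell (29 and 0 adjusted over the list alone), with Utp20 at 1.58 ± 0.12 and Ddx21 at 0.99 ± 0.17. The median was 0.56 and the adjusted p 5.17e-18, but 0.138 with an estimated correlation. The 5 list means, in this order, moved by -0.58, 0.76, 0.86, 0.95 and 0.50 on slide 1 and by -0.48, 1.17, 0.74, 1.69 and 0.64 on slide 2.

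In the remaining lists few members changed in LGR5lo cells. Members higher and lower were 1 and 1 of 52 DNA repair (0 and 0 adjusted over the list alone), 2 and 2 of 45 G1 to S (4 and 3), 3 and 5 of 28 WNT (3 and 6), 3 and 4 of 24 Notch (3 and 7), 0 and 0 of 23 Paneth (0 and 0), 1 and 0 of 21 goblet (0 and 0), 3 and 4 of 35 enteroendocrine (4 and 5), 0 and 1 of 27 tuft (0 and 1), 0 and 0 of 41 enterocyte (0 and 0), 1 and 2 of 32 leukocyte (1 and 2), 2 and 0 of 20 stromal (2 and 0) and 0 and 0 of 8 erythrocyte markers (0 and 0). Camera called 2 of them, the tuft list (median -0.37, adjusted p = 0.0129, but 0.772 with an estimated correlation) and the Paneth list (median 0.53, adjusted p = 0.0271, but 0.772 with an estimated correlation). The Paneth list mean moved by 1.26 on slide 1 and by -0.27 on slide 2, and its call was lost without the array that stands apart (adjusted p = 0.40). Among single members, Cd44 rose (2.25 ± 0.17), as did Tph1, the gene of serotonin synthesis in enterochromaffin cells (2.10 ± 0.29), Vim (1.27 ± 0.21), Jag2 (2.23 ± 0.27) and Jag1 (1.39 ± 0.18), while Lfng (-1.92 ± 0.23) and the T cell gene Cd8a (-1.45 ± 0.32) fell. The Cd8a call was lost without irradiated LGR5lo replicate 3.

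The irradiation effects of the 2 sorts were then set beside each other. Across all genes, which are not independent replicates, the effects correlated with Pearson r of 0.607 and Spearman rho of 0.465. With LGR5hi effects from replicates 1 and 2 and LGR5lo effects from replicates 3 and 4, so that no slide or number is shared, r was 0.569, and with the reverse choice 0.374. On slide 1 alone it was 0.467, on slide 2 alone 0.530, and without the array that stands apart 0.702. Genes called higher in both sorts numbered 1002 against 76.6 expected of independent lists, genes lower in both 570 against 60.4, and 0 went in opposite directions. The slope of LGR5lo on LGR5hi effects over the 1572 genes called in both was 0.73. A further 2171 genes were called in LGR5hi only and 498 in LGR5lo only, but of these 5 had a called difference between the sorts, namely Btbd17, Gprc5b, Gpx3, Hhex and Trim47. Most of the contrast in counts is therefore not a tested difference.

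**Figure D3:**
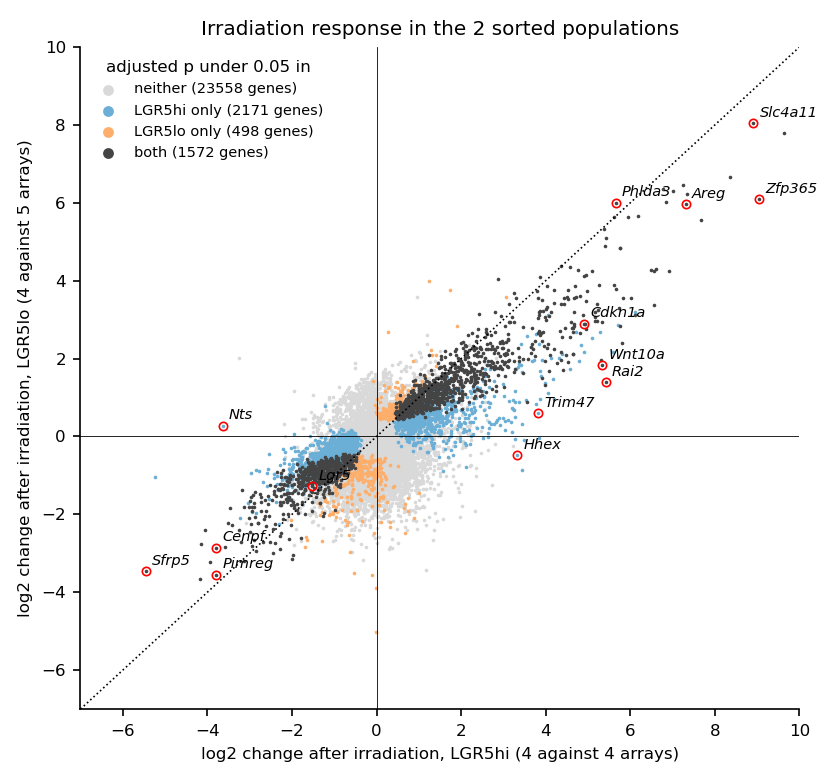
Log2 change after irradiation in LGR5hi (horizontal) and LGR5lo cells (vertical), 1 point per gene, coloured by where the adjusted p is under 0.05; the dotted line marks equal effects. Of 4241 genes called in either sort, 96.1% have the same sign in both, and Rai2, Trim47 and Hhex lie far below the line.

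The difference of the effects asks which genes answered irradiation differently in the 2 sorts. It was called for 11 genes, 10 of which rose more in LGR5hi cells. They were the WNT ligand gene Wnt10a and, with these fitted differences, Rai2 (4.02 ± 0.56; NM_198409, chromosome X, 158217347 to 158217406), the transcription factor gene Hhex (3.81 ± 0.60), Trim47 (3.21 ± 0.47), the extracellular glutathione peroxidase gene Gpx3 (2.95 ± 0.43), the immediate early gene Arc (2.68 ± 0.36), Gprc5b (2.57 ± 0.34), the death-associated kinase gene Dapk1 (2.41 ± 0.36), Btbd17 (2.29 ± 0.35) and the transcript AK035396 (1.32 ± 0.20). The oestrogen receptor gene Gper1 went the other way (-1.45 ± 0.24). Adjusted p ran from 0.024 to 0.048. Rai2 went from -4.53 ± 0.93 to 0.88 ± 0.63 in LGR5hi cells and from -1.25 ± 0.26 to 0.15 ± 0.53 in LGR5lo cells (normalized log2 signal, SD). Of the 10, 8 had been lower in LGR5hi than in LGR5lo cells before irradiation by a call of their own, and Wnt10a was above background on no non-irradiated array, so the size of its difference is not given. Its rise was at least 3.57 log2 in LGR5hi and at least 1.26 log2 in LGR5lo cells, and after irradiation it was 2.34 ± 0.38 higher in LGR5hi cells. Hhex and Gpx3 were above background on 1 of 3 non-irradiated LGR5hi arrays, and Rai2 and Gprc5b on 2 of 3. Cdkn1a differed by 2.01 ± 0.43 by its brightest probe and by 0.51 by its lowest (adjusted p = 0.19), and Lgr5 by -0.26 ± 0.40 (adjusted p = 0.84).

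The count of 11 rests on single arrays. It was 0 without non-irradiated LGR5hi replicate 1 or 2, without irradiated LGR5hi replicate 3 or without irradiated LGR5lo replicate 1, 3 or 4. It was 2 without irradiated LGR5hi replicate 1, 4 without non-irradiated LGR5hi replicate 4 and 26 (24 higher, 2 lower) without non-irradiated LGR5lo replicate 2. With slide as a block it was 2, which share 0 genes with the 11, with number as a block within each arm 16, of which 7 are among the 11, and 0 on slide 1 and on slide 2 alone, where limma gave no gene; 1891 genes had an unadjusted p under 0.05 in the fit of all arrays. No list had a member past the threshold over all genes. The G2 and mitosis list fell more in LGR5hi cells by its camera test, with a median difference of -0.81 log2, 14 of 48 genes lower adjusted over the list alone and an adjusted p of 8.97e-25, but 0.289 with an estimated correlation. Its list mean was -0.72 on slide 1 and -0.68 on slide 2. By pair its mean, LGR5hi minus LGR5lo, ran from 0.33 to 0.53 before irradiation and from -0.41 to -0.07 after it. The reserve or injury-associated list had a median of 0.48, 1 gene higher adjusted over the list alone and an adjusted p of 0.0213, but 0.289 with an estimated correlation. It was the list that passed fry (adjusted p = 0.0068), and its mean was 1.16 on slide 1 and 0.60 on slide 2. By pair its mean, LGR5hi minus LGR5lo, ran from -0.83 to 0.31 before irradiation and from 0.70 to 0.92 after it. The -0.83 is that of pair 2, which holds the array that stands apart, and the other pairs ran from -0.01 to 0.31. Fry was not repeated without that array.

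Camera also called 10 other lists for the difference of the effects, and none of these calls held with an estimated correlation. Lower in LGR5hi cells by the median difference were DNA repair (-0.27, adjusted p = 4.85e-07), G1 to S (-0.23, adjusted p = 0.00015), LGR5 stem cell (-0.26, adjusted p = 0.00015), enteroendocrine (-0.39, adjusted p = 0.0040), enterocyte (-0.45, adjusted p = 0.00051) and erythrocyte markers (-0.82, adjusted p = 0.0155). With an estimated correlation these had an adjusted p of 0.467, 0.471, 0.471, 0.471, 0.610 and 0.467. Higher were p53 targets (0.18, adjusted p = 0.0118, with a list mean of 0.29 that became -0.01 after median centring), leukocyte markers (0.53, adjusted p = 0.0024), stromal markers (0.50, adjusted p = 0.0483) and immediate early genes (0.59, adjusted p = 0.0029). With an estimated correlation these had an adjusted p of 0.471, 0.471, 0.471 and 0.467. By pair, the means before and after irradiation did not overlap for p53 targets (-0.08 to 0.11, then 0.30 to 0.44) or immediate early genes (-0.43 to 0.13, then 0.22 to 0.37). They overlapped for leukocyte and stromal markers and for each of the lists named here as lower in LGR5hi cells. For G1 to S genes they ran from 0.07 to 0.92, then from 0.11 to 0.39. For DNA repair genes they ran from 0.27 to 0.72, then from 0.19 to 0.28. The stromal call was lost without the array that stands apart (adjusted p = 0.18). The leukocyte difference rests on non-irradiated LGR5lo replicates 2, 4 and 5, with list means of -0.53, 0.04 and 0.05 against -1.47 and -1.50 on replicates 1 and 3, while irradiated arrays ran from -1.59 to -1.12 in LGR5hi and from -1.49 to -1.23 in LGR5lo cells. Adjusted over the list alone, limma called 3 p53 targets higher, 1 enteroendocrine marker higher and 3 lower, 2 erythrocyte markers lower, 1 tuft marker and 1 Notch gene higher, and 0 genes of the other lists. Not called were WNT targets (-0.16, adjusted p = 0.12), Paneth (-0.07, adjusted p = 0.70), goblet (-0.39, adjusted p = 0.092) and tuft markers (0.13, adjusted p = 0.076), Notch (0.01, adjusted p = 0.82) and NF-kB genes (0.31, adjusted p = 0.13), the BCL2 family (-0.07, adjusted p = 0.48) and ribosome biogenesis genes (-0.07, adjusted p = 0.16).

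**Figure D4:**
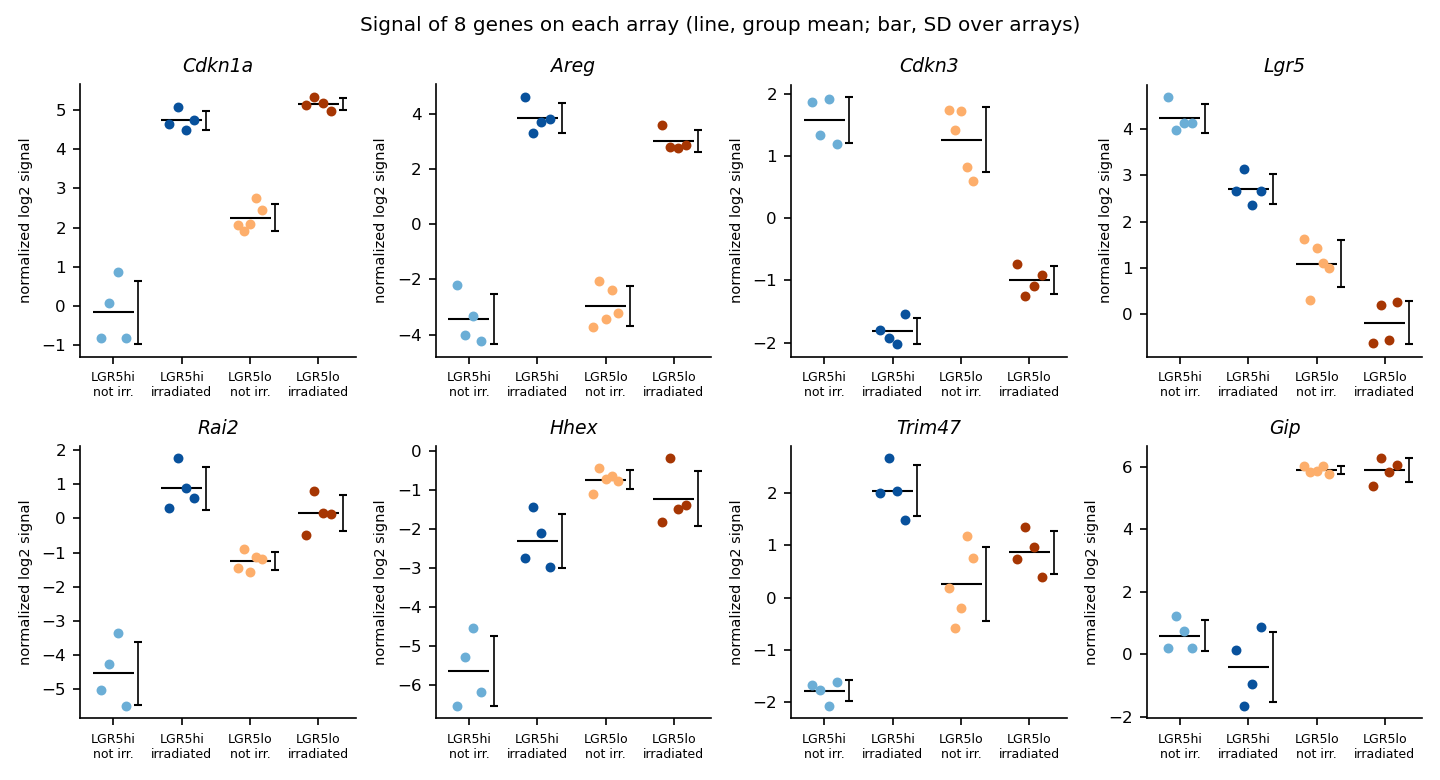
Normalized log2 signal of 8 genes on each array by group; points are arrays, lines are group means and bars are SD over arrays (n = 4, 4, 5 and 4). Cdkn1a starts at -0.17 in LGR5hi and 2.26 in LGR5lo cells and reaches 4.74 and 5.16 after irradiation.

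LGR5hi and LGR5lo cells of non-irradiated mice (4 against 5 arrays) were compared for the baseline difference between the populations. LGR5hi cells held more of the transcripts of LGR5 stem cells and WNT targets, and LGR5lo cells more of those of enteroendocrine cells. Lgr5, the gene behind the sort gate, was 3.14 ± 0.28 log2 higher in LGR5hi cells (NM_010195; chromosome 10, 114887403 to 114887462), which checks the sort and is not independent of it. The other largest differences in this direction were the chemokine receptor gene Ackr3 (3.20 ± 0.57), Tnfrsf19 (2.84 ± 0.22, with probes from 0.97), the oestrogen receptor gene Esr1 (2.76 ± 0.31), Cbs (2.69 ± 0.33), Kif26b (2.50 ± 0.29, with probes from -0.43), Bex1 (2.46 ± 0.43) and Slc38a4 (2.39 ± 0.66). The Slc38a4 call was lost without any of non-irradiated LGR5hi replicates 1, 2, 3 and 4 or LGR5lo replicates 4 and 5. Higher in LGR5lo cells were the alpha-fetoprotein gene Afp (-6.44 ± 0.83), the hormone genes Sst (-5.53 ± 0.69) and Gip (-5.30 ± 0.39), Resp18 (-4.90 ± 0.64), Hhex (-4.90 ± 0.42) and Scgn (-4.87 ± 0.51). St8sia3 and Dner were at least 7.50-fold and 9.38-fold lower in LGR5hi cells. In all, limma called 2646 genes, 1281 higher and 1365 lower in LGR5hi cells, with 353 and 1073 differing at least 2-fold.

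The baseline count was 2869 (1186 and 1683) without the array that stands apart. It was 1443, 1746 and 1655 without non-irradiated LGR5hi replicates 1, 2 and 4, and 4229 and 1682 without non-irradiated LGR5lo replicates 1 and 5. It was 2056 with slide as a block, 106 on slide 1, 246 on slide 2 and 2402 with number as a block within each arm. The median over all genes was -0.08 log2 and 0.16 after median centring.

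Of 44 LGR5 stem cell markers, 36 were higher in LGR5hi cells at baseline and 0 lower (40 and 0 adjusted over the list alone). The median was 1.42 log2 (adjusted p = 3.88e-39, and 0.0038 with an estimated correlation). They included Sp5 (2.27 ± 0.20), Scn2b (2.01 ± 0.17), Ascl2 (1.93 ± 0.22) and Olfm4 (1.90 ± 0.22). Of 28 WNT targets 13 were higher and 3 lower (16 and 5 adjusted over the list alone), with a median of 0.86 (adjusted p = 3.64e-07, and 0.0029 with an estimated correlation). The lower ones included Zcchc12 (-3.45 ± 0.33). The stem cell and WNT lists share members, among them Lgr5 itself, Ascl2, Axin2, Sp5 and Tnfrsf19, so they are not independent results. On slides 1 and 2 the stem cell list mean differed by 1.43 and 1.36 and the WNT list mean by 0.44 and 0.65. By camera at the preset correlation the lists of DNA repair and the cell cycle were also higher in LGR5hi cells. Members higher and lower were 23 and 0 of 52 DNA repair genes (33 and 0 adjusted over the list alone), 16 and 1 of 45 G1 to S genes (30 and 2) and 6 and 0 of 48 G2 and mitosis genes (20 and 0), with medians of 0.54, 0.57 and 0.58. Cdk6, a kinase gene of the G1 list, was 1.49 ± 0.18. Their adjusted p of 7.29e-15, 1.34e-11 and 2.25e-11 became 0.105, 0.195 and 0.314 with an estimated correlation. By pair, the DNA repair mean differed by 0.29 and 0.27 in the female pairs 1 and 3. In the male pairs 2 and 4 it differed by 0.72 and 0.56. The G1 to S mean differed by 0.07 and 0.21 against 0.78 and 0.92. In this arm females lay in row 1 of the slide and males in row 2, so sex and row cannot be told apart here. After irradiation the DNA repair mean differed by 0.23 and 0.21 in the male pairs 1 and 3. In the female pairs 2 and 4 it then differed by 0.28 and 0.19. The G1 to S mean was 2.10, 1.83 and 2.02 on the male non-irradiated LGR5lo replicates 2, 4 and 5, against 2.70 and 2.55 on the female ones; leukocyte markers were higher on the same 3 arrays. The ribosome biogenesis list had 5 and 0 of 42 genes (10 and 0 over the list alone), a median of 0.39 and an adjusted p of 3.81e-09, but 0.314 with an estimated correlation.

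Of 35 enteroendocrine markers 32 were lower in LGR5hi cells at baseline and 0 higher, the same adjusted over the list alone. They had a median of -3.31 log2 (adjusted p = 5.45e-44, and 0.0021 with an estimated correlation). Isl1 (-3.60 ± 0.20), Cpe (-4.05 ± 0.24) and Chgb (-3.93 ± 0.26) were among those with the smallest p. Of 21 goblet markers 17 were lower and 0 higher (18 and 0 adjusted over the list alone), with Tff3 at -2.31 ± 0.20 and Agr2 at -2.44 ± 0.27. Their median was -2.44 and the adjusted p 2.01e-18, but 0.0589 with an estimated correlation. Of 27 tuft markers 24 were lower and 1, Ascl2, higher, the same adjusted over the list alone, with Rgs2 at -3.06 ± 0.30. Their median was -1.89 and the adjusted p 1.67e-18, but 0.0817 with an estimated correlation. Their 3 list means differed by -3.16, -1.75 and -1.59 on slide 1 and by -2.99, -2.20 and -1.54 on slide 2. Among secretory progenitor and Notch genes 4 of 24 were higher and 7 lower (5 and 10 adjusted over the list alone; adjusted p = 0.29), with the lineage factor genes Neurog3 (-2.46 ± 0.21), Gfi1 (-2.37 ± 0.29) and Atoh1 (-2.44 ± 0.33) lower.

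Members of other lists higher and lower in LGR5hi cells at baseline were 1 and 3 of 23 Paneth (1 and 4 adjusted over the list alone), 0 and 3 of 41 enterocyte (0 and 3), 3 and 7 of 32 leukocyte (4 and 8), 0 and 2 of 20 stromal (0 and 2) and 0 and 1 of 8 erythrocyte markers (0 and 1). Camera called the Paneth list (median -0.39, adjusted p = 0.0158, but 0.577 with an estimated correlation), the leukocyte list (median -0.87, adjusted p = 0.0110, but 0.473 with an estimated correlation) and the stromal list (median -0.40, adjusted p = 0.0065, but 0.314 with an estimated correlation). The Paneth mean was 0.02 on slide 1 and -0.91 on slide 2. The stromal mean was -1.21 on non-irradiated LGR5lo replicate 2, the array that stands apart, against a median of -2.83 on the others of its group. The leukocyte mean, given above for each non-irradiated LGR5lo array, was higher on the male replicates 2, 4 and 5, which had the lowest array weights. It ran from -1.61 to -1.27 in non-irradiated LGR5hi cells. Vim (-4.08 ± 0.21) and the cytotoxic granule gene Nkg7 (-2.48 ± 0.33) were lower, and the plastin gene Lcp1 was higher (1.20 ± 0.14). In the p53 list 5 were higher and 3 lower of 50 (5 and 4 adjusted over the list alone; adjusted p = 0.28), and Cdkn1a was -2.43 ± 0.30 by its brightest probe and -0.71 by its highest. For reserve or injury-associated markers, 4 of 16 were higher and 1 lower, the same over the list alone (adjusted p = 0.33), with Clu at 2.29 ± 0.22 and Ly6a at -1.76 ± 0.39. The immediate early list had 3 and 3 of 32 members (adjusted p = 0.42), NF-kB genes 2 and 0 of 27 (adjusted p = 0.58) and the BCL2 family 3 and 2 of 19 (adjusted p = 0.14), each with the same counts adjusted over the list alone.

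After irradiation the sorts were compared with 4 against 4 arrays. Higher in LGR5hi cells were Esr1 (3.12 ± 0.32), Lgr5 (2.89 ± 0.29), Slc14a1 (2.68 ± 0.27), the WNT transcription factor gene Lef1 (2.61 ± 0.42), Pcdh8 (2.60 ± 0.27), Tnfrsf19 (2.54 ± 0.23) and Ldhb (2.51 ± 0.44), and Ebf1 was at least 4.06-fold higher. The Ebf1 call was lost without any of irradiated LGR5lo replicates 1, 3 and 4 or irradiated LGR5hi replicates 2, 3 and 4. Higher in LGR5lo cells were Nts (-7.66 ± 0.60), Sst (-6.66 ± 0.72), Afp (-6.58 ± 0.87), Gip (-6.28 ± 0.41) and Resp18 (-5.42 ± 0.68). St8sia3, Gpr112 and Il18r1 were at least 13.1-fold, 22.4-fold and 10.3-fold lower in LGR5hi cells. Cdkn1a was -0.41 ± 0.31 (adjusted p = 0.58). In all, limma called 1748 genes, 611 higher and 1137 lower in LGR5hi cells, with 318 and 838 differing at least 2-fold. The count was 2868 (1194 and 1674) without the array that stands apart, which enters this comparison only through the shared variance, and 1059 without irradiated LGR5lo replicate 1. It was 2089 with slide as a block, 319 on slide 1, 118 on slide 2 and 2326 with number as a block within each arm. Across genes the sort differences of the 2 arms correlated with r of 0.539, with 378 genes higher in LGR5hi cells in both arms against 28.2 expected, 755 lower in both against 55.8 and 3 opposite. The 3 were Arc, Dapk1 and Gprc5b, each lower in LGR5hi cells before irradiation and higher after it.

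Of 44 LGR5 stem cell markers 29 were higher in irradiated LGR5hi cells than in irradiated LGR5lo cells and 0 lower (36 and 0 adjusted over the list alone), with a median of 1.12 log2. Of 28 WNT targets 11 were higher and 3 lower (12 and 4), with a median of 0.52. Both lists had an adjusted p of 0.0081 with an estimated correlation, but they share members and so are not independent results. Scn2b was 1.85 ± 0.18, Ascl2 2.05 ± 0.23 and Olfm4 2.01 ± 0.24. Reserve or injury-associated markers were higher, 4 and 0 of 16, the same adjusted over the list alone, with Clu at 2.46 ± 0.24 and Ccn1 at 1.76 ± 0.29, a median of 0.85 and an adjusted p of 0.0081 with an estimated correlation. Lrig1, Sox9 and Msi1 are in this list and in the stem cell list. Enteroendocrine markers were lower, 0 and 32 of 35 (1 and 32 adjusted over the list alone), with Chgb at -4.69 ± 0.28, a median of -3.66 and an adjusted p of 0.00036 with an estimated correlation. Goblet markers were lower, 0 and 16 of 21 (0 and 17 adjusted over the list alone), with Klk1 at -3.01 ± 0.28, a median of -2.76 and an adjusted p of 0.0115 with an estimated correlation. Tuft markers were 1 and 15 of 27 (1 and 21 adjusted over the list alone), with a median of -1.64 and an adjusted p of 1.28e-17, but 0.0791 with an estimated correlation. The means of the stem cell, enteroendocrine, goblet and tuft lists differed by 1.29, -3.69, -2.54 and -1.29 on slide 1 and by 1.07, -3.31, -2.04 and -1.30 on slide 2.

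Among the other lists for the irradiated sorts, camera called p53 targets (4 and 0 of 50, the same adjusted over the list alone, median 0.41), DNA repair (0 and 1 of 52, 0 and 0 over the list alone, 0.18), G1 to S (3 and 1 of 45, 6 and 1 over the list alone, 0.33), G2 and mitosis (2 and 1 of 48, the same over the list alone, -0.31), immediate early (6 and 1 of 32, 7 and 2 over the list alone, 0.31), NF-kB (2 and 1 of 27, the same over the list alone, 0.29) and ribosome biogenesis genes (1 and 0 of 42, the same over the list alone, 0.28). With an estimated correlation the adjusted p of these 7 lists was 0.273, 0.371, 0.371, 0.533, 0.325, 0.286 and 0.325. It also called Paneth (1 and 1 of 23, 1 and 2 over the list alone, -0.60), enterocyte (0 and 6 of 41, 0 and 7 over the list alone, -0.92) and erythrocyte markers (0 and 2 of 8, the same over the list alone, -0.91), with adjusted p of 0.425, 0.325 and 0.273 with an estimated correlation. The enterocyte mean was -1.77 on slide 1 and -0.32 on slide 2. Notch genes had 4 and 6 of 24 (6 and 6 over the list alone; adjusted p = 0.46), leukocyte markers 1 and 2 of 32 (the same over the list alone; adjusted p = 0.70), stromal markers 0 and 1 of 20 (the same over the list alone; adjusted p = 0.49) and the BCL2 family 3 and 2 of 19 (7 and 5 over the list alone; adjusted p = 0.46). Gfi1 (-3.10 ± 0.31), Dll4 (-2.20 ± 0.23), Vim (-4.70 ± 0.22), Klf4 (-2.11 ± 0.24) and Hba-a1 (-1.95 ± 0.35) were lower in LGR5hi cells, and Fgfrl1 (1.14 ± 0.24) and Cxcl16 (1.02 ± 0.18) higher.

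**Figure D5:**
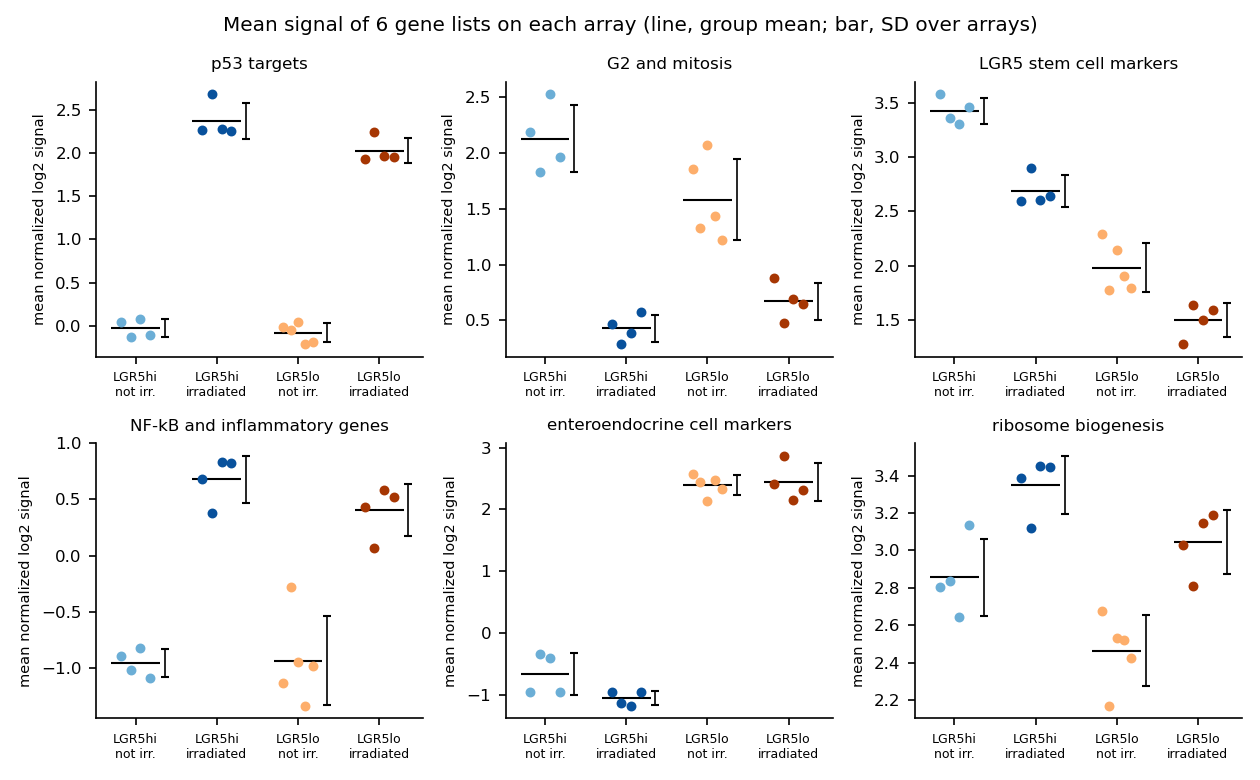
Mean normalized log2 signal of 6 gene lists on each array by group; points are arrays, lines are group means and bars are SD over arrays (n = 4, 4, 5 and 4). The mean of the p53 targets goes from -0.03 to 2.37 in LGR5hi cells and from -0.08 to 2.02 in LGR5lo cells.

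Sex was compared over all groups, as a check of the labels and of the size of a sex difference. Female arrays had higher Xist, the RNA that silences an X chromosome (6.79 ± 0.32), and lower Ddx3y (-8.32 ± 0.15), Eif2s3y (-9.81 ± 0.18), Uty (-4.64 ± 0.17) and Kdm5d (-3.33 ± 0.35). In all, 34 genes were called, 15 higher and 19 lower in females. The count was 79 without non-irradiated LGR5lo replicate 2 and between 18 and 22 without any of 9 others, namely non-irradiated LGR5hi replicates 1 and 2, non-irradiated LGR5lo replicate 3, irradiated LGR5hi replicates 1, 2 and 3 and irradiated LGR5lo replicates 1, 2 and 3. Arrays of a same-numbered pair are not independent, and with arm and number as a random block the count was 18. It was 27 with slide as a block, 3 on slide 1 and 5 on slide 2. The sex-linked list of 9 genes had 0 members called in each of the other comparisons, also adjusted over the list alone, with camera adjusted p of 0.71, 0.50, 0.69, 0.59 and 0.91 in the order given above; at an unadjusted p under 0.05 limma had 6451, 6696, 1891, 6957 and 4966 genes in them.

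The irradiation effect differed between females and males for 2 genes over both sorts. Cpn1, which encodes a carboxypeptidase subunit, differed by 2.89 ± 0.25 (adjusted p = 0.00084) and Hspa1a, an inducible heat shock gene, by 3.94 ± 0.48 (adjusted p = 0.019). Hspa1a was -4.00 ± 0.47 in non-irradiated females (n = 4), -0.02 ± 0.93 in non-irradiated males (n = 5), -1.94 ± 0.36 in irradiated females and -1.99 ± 0.42 in irradiated males (normalized log2 signal, SD, n = 4 each). The row of the array on its slide is the same contrast as this one, so the 2 cannot be told apart. The arrays of each sex in an arm come from 2 pairs, and the male non-irradiated LGR5lo replicate 5 has no partner; with arm and number as a random block the count was 1. The count was also 1 with slide as a block, and on slide 1 and on slide 2 alone limma called 0 genes. It stayed at 2 without non-irradiated LGR5hi replicate 1 or 4, non-irradiated LGR5lo replicate 2 or 4 or irradiated LGR5lo replicate 3, and was 1 without any other array; 1564 genes had an unadjusted p under 0.05.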

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

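The tests of explanations in this part were all chosen only after the results were seen, while the tests of differences between effects were planned. The fall of G2 and mitosis genes after irradiation in LGR5hi cells may have technical or compositional causes, of which 2 were tested. A lower share of cycling cells would lower G1 to S genes along with them; the mitosis list mean minus the G1 to S list mean changed by -1.34 (exact p = 0.0286, the smallest that 70 splits can give), and in LGR5lo cells by -0.84 (exact p = 0.00794, the smallest that 126 can give). In LGR5lo cells the G1 to S list mean changed by -0.07 (exact permutation p = 0.714) and the mitosis list mean by -0.91. The G1 to S mean varied widely over the non-irradiated LGR5lo arrays, with an SD of 0.37. The change of the G1 to S list was 0.214 of that of the mitosis list in LGR5hi cells, while the differences between the sorts in the 4 non-irradiated pairs had ratios from 0.218 to 1.73, so this test decides nothing. The scaling that brings the list nearest 0 still gives a mean of -1.66, which argues against scaling. Among the causes that stay open are a lower share of cycling cells and a block before mitosis, the latter untested.

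Immediate early genes were higher after irradiation, and stress from dissociation and sorting could have added to it. Heat shock genes, which such stress also induces, changed by 0.237 of the median change of the other members in LGR5hi cells. The ratio runs from -0.07 to 0.54 when 1 of the 4 is left out, and only Hspb1 among them was called (1.80, adjusted p = 0.0405). Hspa1a, 1 of the 4, already varied among non-irradiated arrays of both sorts. It was -4.00 ± 0.47 in females and -0.02 ± 0.93 in males (normalized log2 signal, SD). The heat shock test therefore decides nothing, and its bound was made stricter after its value had been seen. The fastest immediate early genes, which handling stress would raise at least as much, had a median change of 1.503 against 1.39 for the other members in LGR5hi cells (5 of 8 called), but 0.79 against 0.84 in LGR5lo cells (2 of 8 called). Handling stress and a response to irradiation therefore both stay open.

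A larger rise in LGR5hi cells was called for 10 genes, 8 of which were lower there at baseline by a call, so expression in other cells of the LGR5lo sort may hide a shared rise. On the linear scale the ratio of the rises, LGR5lo over LGR5hi, lay below 0.328, the 5th percentile of the 831 genes higher in both sorts that had no called difference at baseline or between the effects, for 8 of the 10, with Gpx3 at 1.44 and Rai2 at 0.38 as the exceptions. Hhex was below that bound at -0.68, as its linear mean did not rise in LGR5lo cells but went from 0.60 to 0.47. AK035396 had linear means of 1.93 in LGR5hi and 1.84 in LGR5lo cells before irradiation (limma adjusted p = 0.76), so it lacks the lower baseline. The genes were picked for a large difference, which favours low ratios and a lower baseline in LGR5hi cells. This test therefore decides nothing, and masking stays open for the genes that were lower at baseline. Without non-irradiated LGR5lo replicate 2, whose dim probes were lifted, 10 of the 10 were still past the threshold, which argues against that array as their cause. A biological difference between the sorts stays open as well.

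The differences between the irradiation effects of the sorts, tested as such, were 4.02 for Rai2, 3.81 for Hhex, 3.21 for Trim47, 2.95 for Gpx3, 2.68 for Arc, 2.57 for Gprc5b, 2.41 for Dapk1, 2.29 for Btbd17, 1.32 for AK035396 and -1.45 for Gper1. For Wnt10a the fitted value of 3.50 is no measure of size, as no non-irradiated array was above background. Leaving out single arrays takes this count of 11 to between 0 and 26, as given in the report. Differences of list means with a camera call were 0.29 for p53 targets, -0.29 for DNA repair, -0.29 for G1 to S, -0.79 for G2 and mitosis, -0.26 for LGR5 stem cell markers, 0.85 for reserve or injury-associated markers, -0.44 for enteroendocrine, -0.49 for enterocyte, 0.87 for leukocyte, 0.59 for stromal and -1.23 for erythrocyte markers, and 0.52 for immediate early genes. With an estimated correlation 0 of these 12 were called, their adjusted p running from 0.289 to 0.610. Several of these means depend on the scaling by more than 1.5 times. Under quantile normalization they were 0.19 for p53 targets, 0.15 for stromal and 0.34 for immediate early genes. After median centring they were -0.01 for p53 targets, -0.58 for DNA repair, -0.59 for G1 to S, -0.56 for LGR5 stem cell, 0.55 for reserve, -0.74 for enteroendocrine, -0.78 for enterocyte, 0.57 for leukocyte, 0.30 for stromal and 0.22 for immediate early genes. Between the sexes the irradiation effects differed by 2.89 for Cpn1 and 3.94 for Hspa1a, which cannot be told apart from the row on the slide.

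Arrays far from the rest of their group were sought by Dixon's ratio, the gap to the nearest array over the range of the group, at its 95% critical value. It was passed in 48 of 680 groups, where chance gives about 1 in 20, so a large part of the 48 may be chance. Of the 48, 10 lay on non-irradiated LGR5lo replicate 2. On that array they were the median correlation with its group (0.859; 0.915 against 0.970), the reserve (0.830) and stromal lists (0.733), Tubb6 (0.846), Prelp (0.846), Mdm2 (0.862), Egr1 (0.757), Lef1 (0.808), Ndrg1 (0.742) and Kcnj11 (0.846). Replicate 4 of that group had a spike-in slope of 0 (0.797), and replicate 1 a lower interferon list (0.830). On irradiated LGR5hi replicate 2 they were the p53 list (0.934; 2.68 against a median of 2.26) and the stem cell list (0.867), Notch3 (0.941), Phlda3 (0.835), Plk2 (0.851), Mdm2 (0.844), Ier3 (0.864), Gpx3 (0.881), Dapk1 (0.922), Cbs (0.870) and Fgfrl1 (0.861). On irradiated LGR5lo replicate 2 they were the p53 list (0.879; 2.24 against 1.95), Plk2 (0.926), Wnt10a (0.907), Neurog3 (0.932) and Ldhb (0.880).

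The others were spread over further arrays. In non-irradiated LGR5hi cells replicate 3 stood apart in the 75th percentile of the signal (0.842; 702 against 408), Akr1c14 (0.874) and Fosl1 (0.878), replicate 1 in the Notch list (0.873), Alox5 (0.8292) and Oas2 (0.842), replicate 2 in Neurog3 (0.944) and Abcc8 (0.846), and replicate 4 in Mdm2 (0.874), Bard1 (0.830) and Sst (0.889). The 408 is that of the readable part of replicate 1. In irradiated LGR5hi cells replicate 3 stood apart in the spike-in slope (0.918), Rgs2 (0.920) and Dnajc3 (0.865), and replicate 4 in the BCL2 list (0.912) and Lef1 (0.861). In irradiated LGR5lo cells replicate 3 stood apart in the 75th percentile (0.874; 691 against 546), replicate 4 in the BCL2 list (0.850) and Klk1 (0.867), and replicate 1 in Areg (0.870).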

How the results depend on the processing

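Fits within 1 slide, without particular arrays and with number as a block within each arm were tests chosen after the data had been seen, and the other settings were planned. Counts of genes were called stable where they stayed within 1.5 times the reported count. The cause of each change below was not tested, except that fits within a slide, without arrays or of only the compared groups use fewer arrays.

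Median centring gave 2355 genes for irradiation in LGR5hi cells, 1273 in LGR5lo cells, 2 for the difference of the effects, 1053 for the sorts after irradiation, 14 for sex and 1 for sex by irradiation. Normexp correction gave 2300 for irradiation in LGR5hi cells, 2 for the difference, 982 for the sorts before irradiation and 12 for sex. Quantile normalization gave 21 for sex and 0 for sex by irradiation, where limma had 1172 genes at an unadjusted p under 0.05. Probes above background on every array gave 7 for the difference.

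Array weights gave 7220 for irradiation in LGR5hi cells, 3495 in LGR5lo cells, 62 for the difference, 5062 for the sorts after irradiation and 129 for sex. A random block of arm and number gave 43 for the difference, 4183 and 2889 for the sorts before and after irradiation, 18 for sex and 1 for sex by irradiation. A slide block gave 2 for the difference and 1 for sex by irradiation, and number as a block with sex as a covariate 26 for the difference. A trended and robust variance gave 59 for sex. Fits of only the compared groups gave 788 for irradiation in LGR5lo cells and 1158 and 3115 for the sorts before and after irradiation; for the difference of the effects they are the fit as reported.

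Slide 1 alone gave 266 and slide 2 alone 1571 for irradiation in LGR5hi cells, 44 and 459 in LGR5lo cells, 0 and 0 for the difference, 106 and 246 for the sorts before irradiation, 319 and 118 after it, 3 and 5 for sex and 0 and 0 for sex by irradiation. At an unadjusted p under 0.05 limma had 725 and 1220 genes for the difference and 1008 and 2123 for sex by irradiation on the 2 slides. Without non-irradiated LGR5lo replicates 2 and 4 the counts were 5683 for irradiation in LGR5hi cells and 3192 for the sorts after irradiation. With number as a block within each arm and without the pair of non-irradiated replicate 2 they were 94 for the difference and 5757 for the sorts after irradiation.

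Leaving out 1 array gave 2837 (without non-irradiated LGR5hi replicate 1) to 5193 genes for irradiation in LGR5hi cells, 1178 to 2542 in LGR5lo cells, 0 to 26 for the difference, 1443 to 4229 and 1059 to 2868 for the sorts before and after irradiation, 18 to 79 for sex and 1 to 2 for sex by irradiation; the arrays behind the other ranges are named in the report. The correlation of the effects was 0.702 without non-irradiated LGR5lo replicate 2. Without that array camera called 9, 9, 12, 16 and 19 lists in the order of the report. With an estimated correlation it called 5 lists for irradiation in LGR5hi cells, 4 in LGR5lo cells, 0 for the difference and 3 and 5 for the sorts before and after irradiation. Fry called 1 for the difference and 10 for the sorts after irradiation.

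For lists called in the report or in the alternative, camera's direction reversed for the Paneth list on slide 2 for irradiation in LGR5lo cells (mean -0.27) and for the difference (0.67), and on slide 1 for the sorts before irradiation (0.017), the enterocyte list on slide 2 for the difference (0.48), and, under quantile normalization, the ribosome list for the difference (0.043). It also did for the glycolysis list for irradiation in LGR5lo cells under quantile normalization, at an adjusted p of 0.957, although the list mean stayed positive (0.19 against 0.21). Camera was not run after median centring, where the mean of the called p53 list changed sign for the difference (-0.01), and means of called lists moved by over 1.5 times for irradiation in LGR5lo cells (LGR5 stem cell -0.23, Paneth 0.71, tuft -0.18, BCL2 0.75, unfolded protein 0.47 and glycolysis 0.46) and for the sorts before irradiation (Paneth -0.24, ribosome 0.64 and unfolded protein -0.28). Under quantile normalization they did so for the unfolded protein list for irradiation in LGR5lo cells (0.14) and the stromal list before irradiation (-0.38). Means of uncalled lists that changed sign with the scaling for irradiation in LGR5lo cells were those of DNA repair (0.13 after median centring), G1 to S (0.18), WNT (0.21, and 0.09 under quantile normalization), interferon (0.21 and 0.10) and sex-linked genes (0.08 and 0.10), and, under quantile normalization, stromal (0.16), goblet (-0.01) and enteroendocrine markers (-0.01). In the other comparisons uncalled lists did so as well. Over all alternatives, 15082 values of the genes chosen by the rule kept their side of the threshold, 1291 no longer passed it, 212 newly passed it and 0 reversed. For the lists these numbers were 1114, 115, 37 and 6. A reversal was counted only where the value passed the threshold in the report or in the alternative. Changes of sign in values uncalled in both are therefore not counted. Signal over background limits the dim genes: from 58.9% to 73.9% of spots were well above it on 16 arrays.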

Other observations

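The splits that part or keep pairs, with or without slide as a block, and the fit without 1 array were tests chosen only after the results were seen, and the gene lists and the other splits were planned. Genes of the interferon response, of the unfolded protein and integrated stress response and of glycolysis and hypoxia were tested as lists beside those of the report. In LGR5hi cells irradiation raised 3 and lowered 2 of 33 interferon genes (4 and 3 adjusted over the list alone; adjusted p = 0.71), and in LGR5lo cells 3 and 0 (3 and 1; adjusted p = 0.77). Mx1, an antiviral gene, rose by 4.65 ± 0.45 and 2.67 ± 0.43, and Tap1, a peptide transporter gene, by 1.62 ± 0.26 and 1.37 ± 0.24. Before irradiation 1 interferon gene was higher and 5 lower in LGR5hi cells (1 and 7 adjusted over the list alone; adjusted p = 0.065), with Usp18 at -2.34 ± 0.25 and Oas2 at -1.74 ± 0.23. After irradiation 0 were higher and 3 lower (0 and 4 adjusted over the list alone), with an adjusted p of 0.0040, but 0.286 with an estimated correlation. For the difference of the effects the interferon median was -0.08 and the mean 0.08 (adjusted p = 0.64). The list's median and mean also had opposite signs for irradiation in LGR5hi cells (-0.22 and 0.04).

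Of 31 genes of the unfolded protein and integrated stress response, 2 rose and 0 fell after irradiation in LGR5hi cells (the same adjusted over the list alone), with an adjusted p of 0.0413, but 0.676 with an estimated correlation. In LGR5lo cells 2 rose and 0 fell (1 and 0 adjusted over the list alone), with an adjusted p of 0.0028, but 0.670 with an estimated correlation. Both calls were lost without non-irradiated LGR5lo replicate 2 (adjusted p = 0.0605 and 0.0568). Sesn2, also a p53 target, rose by 2.68 ± 0.16 and 2.39 ± 0.15. In LGR5hi cells against LGR5lo cells 1 was higher and 8 lower before irradiation (1 and 16 adjusted over the list alone; median -0.69, adjusted p = 6.14e-05, but 0.320 with an estimated correlation), and 1 and 6 after it (1 and 12; median -0.61, adjusted p = 1.46e-06, but 0.273 with an estimated correlation). Dnajc3, which encodes a chaperone partner of the endoplasmic reticulum, was lower by -0.81 ± 0.16 and -1.07 ± 0.17. For the difference of the effects the median was 0.06 (adjusted p = 0.69).

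Of 24 glycolysis and hypoxia genes, 4 rose and 3 fell after irradiation in LGR5hi cells (6 and 3 adjusted over the list alone; adjusted p = 0.39). In LGR5lo cells 3 rose and 1 fell, the same adjusted over the list alone, with an adjusted p of 0.0332, but 0.731 with an estimated correlation and 0.382 without non-irradiated LGR5lo replicate 2. Ndrg1 fell by 1.38 ± 0.27 in LGR5hi cells. In LGR5hi cells against LGR5lo cells 1 was higher and 5 lower before irradiation, the same adjusted over the list alone (adjusted p = 0.12), and 0 and 2 after it, the same adjusted over the list alone (adjusted p = 0.0040, but 0.325 with an estimated correlation). For the difference of the effects the median was -0.12 and the mean 0.04 (adjusted p = 0.30).

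Splits of the same arrays into groups of the same sizes were fitted for each count of genes, on genes without missing values. For irradiation in LGR5hi cells 1 of 35 splits, the real one, gave as many as 3733 genes, with a highest other of 0. For irradiation in LGR5lo cells it was 1 of 100 (2064 genes, highest other 967) and for the sorts after irradiation 1 of 35 (1745, highest other 1). For the sorts before irradiation 2 of 100 gave as many as 2646, with a highest other of 4207. That other split calls more genes than the real one and so reflects structure among the samples. The shares of the 4 counts are under 0.05, so chance can be excluded by this measure, which for the sorts ignores the pairs. The splits that part every same-numbered pair of an arm, as the real ones do, are too few for a share under 0.05. Before irradiation 13 of them were drawn, with 2646 genes in the real one and a highest other of 3, and after irradiation there were 8, with 1745 and a highest other of 0.

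For sex 1 of 100 splits gave as many as 34 genes (highest other 1), and for sex by irradiation 3 of 100 gave as many as 2 (highest other 25), but the drawn splits were not held to keep the same-numbered pairs together, as the real one does. Among the 36 splits that keep the pairs together 3 gave as many for sex (highest other 937) and 6 for sex by irradiation (highest other 735). For sex the other 2 (879 and 937 genes), and for sex by irradiation 2 of the others (699 and 735), part the arrays by slide and reflect a difference between slides; the remaining splits for sex gave at most 9. With slide as a block the count for sex was 27 in the real split and at most 0 in the others, but the 17 splits then left are too few for a share under 0.05. For sex by irradiation 7 of these 17 gave as many as the real 1 (highest other 29). Chance can therefore be excluded for the sex count only by the drawn splits, and cannot be excluded for sex by irradiation. For the difference of the effects 6 of 100 splits gave at least 11 genes, with a highest other of 1395. Those splits mix irradiated with non-irradiated arrays, so they carry irradiation effects of their own, and they ignore the pairs. With the difference within each pair as the value, 1 of 35 splits of the 8 pairs, the real one, gave as many as 16 genes, with a highest other of 0. Chance can be excluded for that count only if same numbers are read as pairs. The planned splits do not exclude it for the 11.

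Without non-irradiated LGR5lo replicate 2 the difference of the effects was called for 26 genes, which include the 11 of the report. Of the 26, 24 rose more in LGR5hi cells or fell less. Among the added ones, picked after their values were seen, were the subunits of the ATP-sensitive potassium channel Abcc8 (1.67, adjusted p = 0.0320) and Kcnj11 (1.46, adjusted p = 0.0422), and Eif4e3 (2.60, adjusted p = 0.0422).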
